A study of Neurospora crassa with 10 samples.

How the data were processed

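The series profiled newly incorporated FLAG-tagged histone H3 by chromatin immunoprecipitation and sequencing in germinated conidia of Neurospora crassa. The labels give 10 libraries in 5 groups of 2: wild type and deletions of dim-2, dim-5, hda-1 and hpo. Per the labels' protocols, cultures were grown for 18 h at 32 °C in the dark, treated with 100 mM hydroxyurea for 3 h, exposed to 465 nm blue light for 2 min and crosslinked with 0.5% formaldehyde. The submitters' processing notes name Bowtie2, HOMER, SICER and deepTools, and their versions and settings are not given in the sources used here. Values of the single libraries were not analysed here, so no comparison between genotypes was made and read depth is unknown.

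The authors deposited 4 interval lists of genes by wild-type expression and 1 list of wild-type H3K9me3 domains, and the columns used were start and end positions. In the deposited gene lists the score is 0 and the strand is + in all 9729 rows, so neither was used. The source, unit and culture conditions, light included, of the expression ranking are not given in the sources used here. The names of the lists were taken as percentiles that rise with expression, which the labels do not state for the middle lists. The order of the middle lists was read from gene length, locus tag numbers and the placement of gene families. Domain lengths, counted with both end positions included, were multiples of 300 bp for 337 of 346 domains, and 10 empty rows of the domain list were skipped. Intervals were read as counting from 0 and are given here counting from 1.

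Genes were named from a table of gene names and positions for the NC12 assembly. Of the 9729 intervals, 9490 had the same position there. Another 238, on linkage group VI between 1851685 and 2769626, had the mirrored position, so the files use a build in which this segment of 918 kb is inverted, and coordinates are given as in the files. The 9 domains off the 300 bp grid all lie on VI. As deposited, domains covered 3.97 kb of genes in that segment; mirrored, they would cover 67.0 kb, so genes and domains were used in 1 orientation as deposited. The remaining interval, on III at 1584834 to 1585858, stayed unnamed. No genome sequence, strand or product description was used.

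A gene overlapped a domain when they shared at least 1 bp. Odds ratios have Woolf 95% intervals, which treat genes as independent and can be too narrow where neighbouring genes are alike. Their p-values come from an exact rotation test: genes were laid in genome order with the linkage groups joined end to end, the list labels were rotated through all 9729 positions, and the observed count was compared with all rotations, two-sided, so that the smallest p is 0.000103. The same test was used for the difference of median distances. Gene length and adjacent pairs were tested by permuting list labels with 100000 and 10000 resamples. Gene lists were tested by Fisher's exact test with Benjamini-Hochberg adjustment. This test treats genes as independent, so its p-values can be too small where listed genes are neighbours. The threshold was 0.05. Shares have Wilson 95% intervals that cover counting error only.

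Designs, a set of alternative settings and 7 gene lists with 59 genes, all found in the files, were fixed before the data were examined; further settings were added later and are named as such with their values. The rule for named genes took every member of these lists, the 10 highest-list genes with the most bases in a domain, and the 5 longest domains with their genes. Genes named outside that rule, such as examples of completely covered genes and the ends of runs of lowest-list genes, were chosen after their values were seen. Another 17 lists by families of gene symbols were chosen after the files were examined and before any was tabulated by expression list. Lists by product description and the planned comparison of GC content were not run.

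The tests were tested on simulated data with the 9729 gene positions. List labels were cut from a simulated series in which neighbouring genes correlated at 0.5. That correlation fades within a few genes, whereas in the data 26.7% of genes 20 apart still shared a list, against 25% by chance. The rejection rates therefore hold for clustering of shorter range than in the data. With no effect, the rotation test rejected 4.5% of 200 simulated sets for domain overlap of the lowest list, where Fisher's exact test rejected 5.5%. For a flag clustered at linkage group ends they rejected 5% and 21.5%. Planted odds ratios of 1.5 and 3 for domain overlap were recovered at a median of 1.49 and 3.02, and 71% and 100% of those sets were rejected. For median distance to a domain, 0 of 20 sets without an effect were rejected, and 100% of 20 sets with one. The permutation test of adjacent pairs rejected 10% of 20 sets of uncorrelated labels and 100% of 20 sets cut from a series correlated at 0.2. Alternatives changed the overlap required, the domains used, the genes used, the distance to an end, the test and the gene lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.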

Results

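The study followed the replacement of histone H3 in germinated conidia of the filamentous fungus Neurospora crassa. A FLAG-tagged copy of histone H3 was placed under the promoter of vvd, a gene induced by blue light, at the his-3 locus. Cultures grown for 18 h in the dark at 32 °C received 100 mM hydroxyurea for 3 h to block DNA replication, and a 2 min pulse of 465 nm light then switched the tagged histone on. Chromatin immunoprecipitation with FLAG beads was labelled for 10 libraries in 5 groups of 2: wild type and deletions of dim-2, dim-5, hda-1 and hpo. Values per library were not analysed here, so turnover was not compared between genotypes, and the depth of the libraries is unknown.

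The files analysed hold the wild-type reference features of the study: 1 list of 346 domains of H3K9me3, the histone mark of constitutive heterochromatin, and 4 lists of genes ranked by wild-type expression, with 9729 genes in all. As their names were read, the lists held the lowest 25% (2433 genes), the 25-50% part (2431), the 50-75% part (2432) and the highest 25% (2433). They carry positions only, with no expression value, strand or peak height. Replicates behind the lists cannot be separated, so the tests below compare groups of genes along the genome, and genes are not independent replicates. The question addressed is how gene expression in the wild type is laid out relative to the heterochromatin in which turnover was to be measured.

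H3K9me3 domains held few genes and varied widely in length. The 346 domains covered 6556 kb, or 16.2% of the 40.5 Mb spanned by the listed features of the 7 linkage groups. Their median length was 9.6 kb (interquartile range 3.3 to 20.9 kb), and 9 domains longer than 100 kb held 29.4% of all domain sequence. Listed genes made up 1.73% of domain sequence against 67.1% of the sequence outside domains. When the domains were rotated at random along their own linkage groups 10000 times, the genic share inside them averaged 56.4% and never fell under 39.7% (two-sided permutation p = 1e-04, the smallest these permutations can give).

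The longest domain of each linkage group was 206.1 kb on I, 211.2 kb on II, 284.4 kb on III, 216.9 kb on IV, 232.8 kb on V, 188 kb on VI and 349.2 kb on VII. The 5 longest together overlapped 10 genes. On VII, 2134501 to 2483700, the domain touched NCU02450 and NCU02438 at its edges and held no complete gene. The domain on III, 683401 to 967800, held NCU05742 (lowest list) and NCU07815 (50-75% list) completely. On V, 890401 to 1123200, both overlapped genes, NCU09669 and NCU09667, were in the lowest list. On IV, 872101 to 1089000, NCU04963 and NCU04983 of the highest list and NCU04974 of the lowest list were overlapped, and on II, 1155001 to 1366200, NCU05338 of the highest list. Domains covered from 14.4% of linkage group V to 20.3% of VII, and a domain lay at both outermost positions of every linkage group, where the ends were taken as the outermost listed feature.

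**Figure D1:**
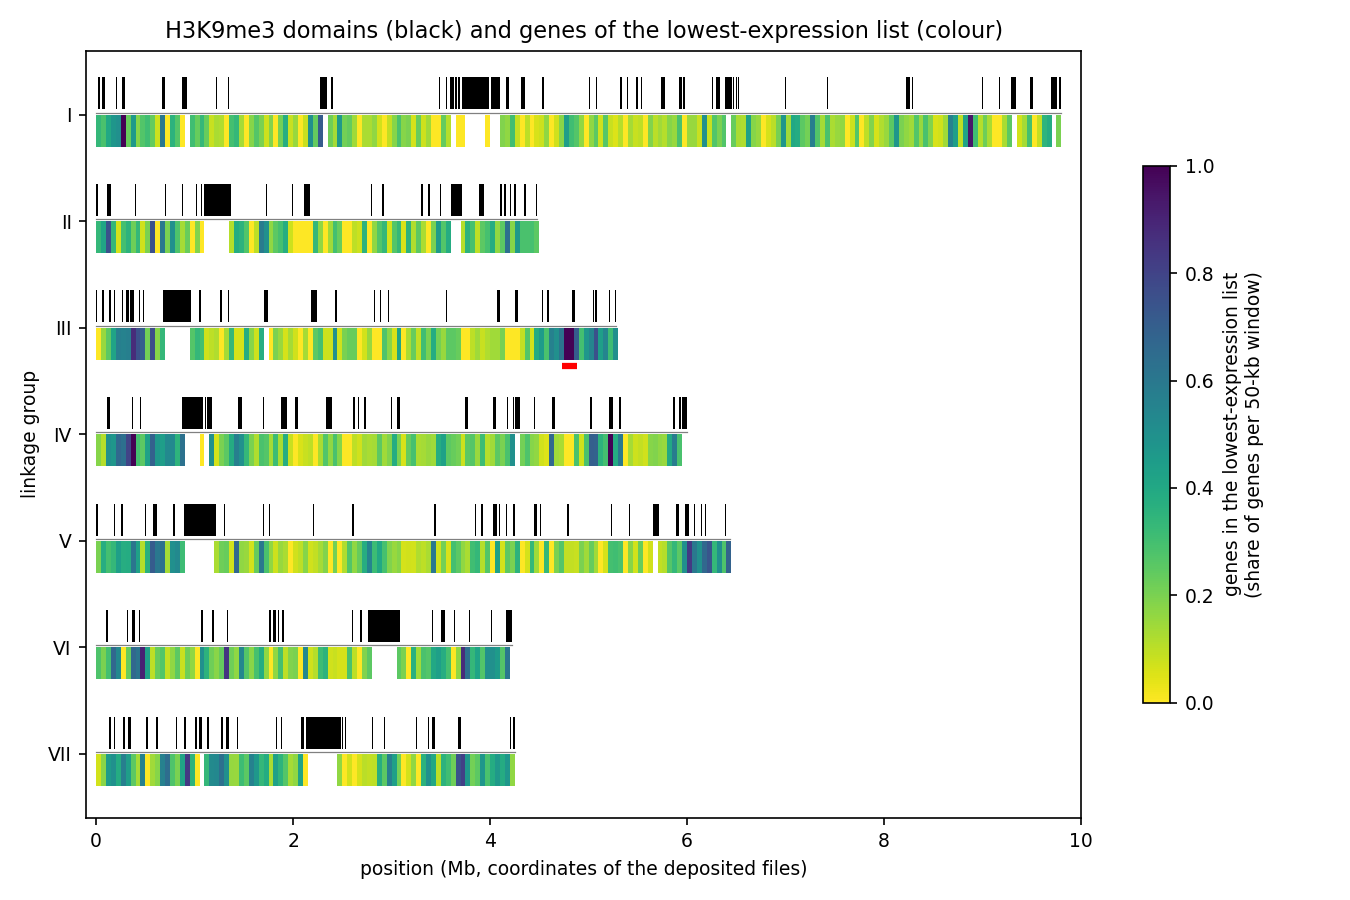
Map of the 7 linkage groups, with position in Mb on the horizontal axis. Black blocks are the 346 H3K9me3 domains, and the strip under each is coloured by the share of genes in the lowest-expression list per 50-kb window (windows with fewer than 4 genes are blank). The red bar on III marks 48 consecutive genes of the lowest list at 4725647 to 4878077.

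Few genes reached into a domain, and those that did came from all 4 expression lists. Of the 9729 genes, 211 (2.17%) overlapped a domain by at least 1 bp. They were 65 genes of the lowest list (2.67%, Wilson 95% interval 2.10 to 3.39), 41 of the 25-50% list (1.69%, 1.25 to 2.28), 49 of the 50-75% list (2.01%, 1.53 to 2.65) and 56 of the highest list (2.30%, 1.78 to 2.98). Overlapped genes of the lowest list had a median of 37.8% of their length covered. The medians were 14.0% in the 25-50% list, 9.21% in the 50-75% list and 11.9% in the highest list. At the 1 bp threshold, genes of the lowest list did not overlap domains significantly more often than the rest. The odds ratio was 1.34 (95% interval 1.00 to 1.81, exact rotation test over 9729 positions, two-sided p = 0.0947). The highest list did not differ from the rest either, with an odds ratio of 1.09 (0.797 to 1.48, exact rotation p = 0.642).

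Among genes that lay mostly inside a domain, a part of the overlapped genes, the lowest list had the largest share. Of 52 genes with at least 50% of their length covered, 29 were in the lowest list, 7 in the 25-50% list, 7 in the 50-75% list and 9 in the highest list. Of 31 genes covered completely, 22 were in the lowest list, among them NCU08083 and NCU08585 on I, NCU05742 on III and NCU04974 on IV. With at least 50% coverage required, the odds ratio of the lowest list was 3.81 (2.20 to 6.61, exact rotation p = 0.000103, the smallest the test can give). Stratified by decile of gene length it was 1.53 (0.763 to 3.07, Mantel-Haenszel chi-square p = 0.215), and without linkage group I it was 6.35. Both of these settings were chosen after the 3.81 had been seen.

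**Figure D2:**
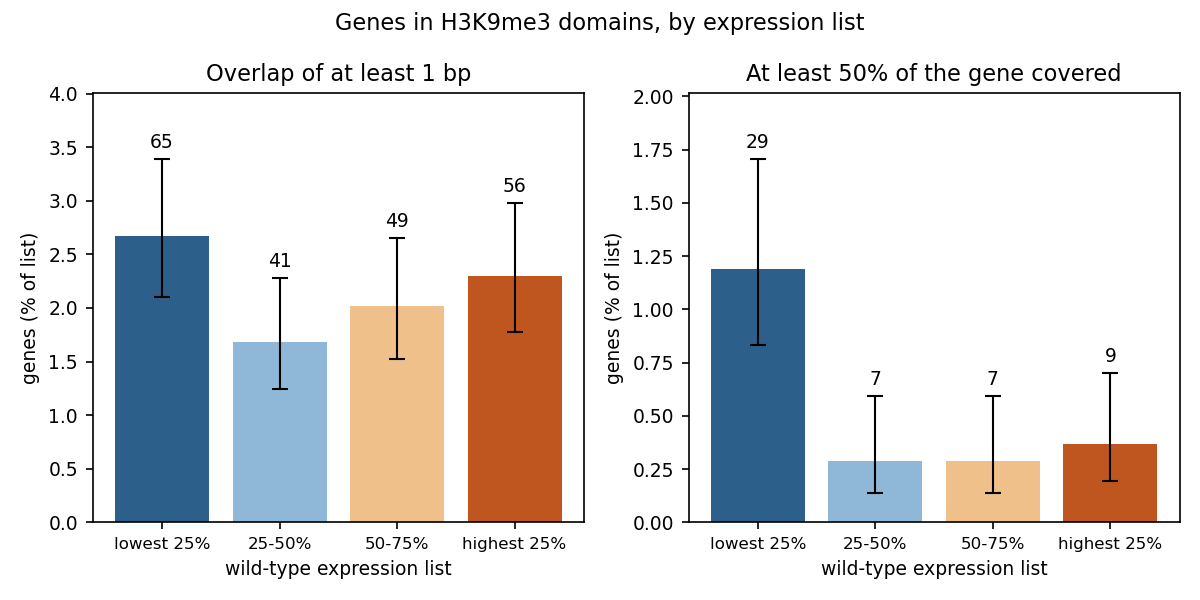
Percentage of the genes of each wild-type expression list that overlapped an H3K9me3 domain by at least 1 bp (left) or had at least 50% of their length covered (right). Bars are shares of the genes of each list, error bars are Wilson 95% intervals that cover counting error only, and the number of genes stands above each bar; the lowest list holds 65 of 211 genes on the left and 29 of 52 on the right.

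Within single linkage groups, neither list stood apart after adjustment. On linkage group III, 11 of the 20 overlapped genes were in the lowest list (odds ratio 3.57, 1.47 to 8.69), and on IV 17 of 35 (2.72, 1.39 to 5.33). The odds ratio was 0.891 on I, 0.424 on II, 1.15 on V, 1.17 on VI and 0.854 on VII. None of the 14 tests of the lowest and highest list within single linkage groups passed after Benjamini-Hochberg adjustment (exact rotation test, unadjusted p = 0.0175 and adjusted p = 0.123 for both III and IV).

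Of the 10 highest-list genes with the most sequence in domains, 7 lie on linkage group I. The highest-list gene with the most domain sequence was NCU09968 on VI (309546 to 315476), with 3176 bp or 53.5% of its length in a domain. NCU08578 on I (3730153 to 3734738) followed with 3086 bp (67.3%). NCU10073 (4040179 to 4043224), NCU09900 (4007554 to 4009650), NCU09892 (3972683 to 3974681), NCU10069 (4333774 to 4335128) and NCU09802 (4095695 to 4096940), all on I, were covered completely, as was NCU00995 at 6456247 to 6457409 of the same linkage group. NCU04963 on IV (872084 to 874450) was covered over 99.3% of its length, and NCU08331 on IV (2379339 to 2383559) over 20.4%. These 6 completely covered genes were the only ones of the highest list, and all 6 lie on I; no test of their placement was run.

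Weakly expressed genes lay closer to heterochromatin than highly expressed ones. The median distance from a gene to the nearest domain was 32.7 kb in the lowest list, 38.7 kb in the 25-50% list, 41.0 kb in the 50-75% list and 43.9 kb in the highest list. The lowest list held 30.2% of the 939 genes lying under 5 kb from a domain without overlapping it (27.4 to 33.3), 27.9% at 5 to 20 kb, 25% at 20 to 50 kb and 22.1% of the 4111 genes at 50 kb or more (20.9 to 23.4). The highest list went the other way, from 21.5% under 5 kb to 27.1% at 50 kb or more. The difference of medians, highest minus lowest, was 11.2 kb over all genes (exact rotation test, two-sided p = 0.00247), and without the 211 overlapping genes it was also 11.2 kb (exact rotation p = 0.00284). Among genes outside domains, the odds ratio of the lowest list for lying under 5 kb from a domain was 1.35 (1.17 to 1.57, exact rotation p = 0.00504), a cut-off chosen after the files were examined. Neither the difference of medians nor this odds ratio was stratified by gene length or repeated without genes near linkage group ends. Neither was compared within single linkage groups. Linkage groups differed in domain cover and in their share of lowest-list genes, and the rotation joins them, so such differences may contribute.

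**Figure D3:**
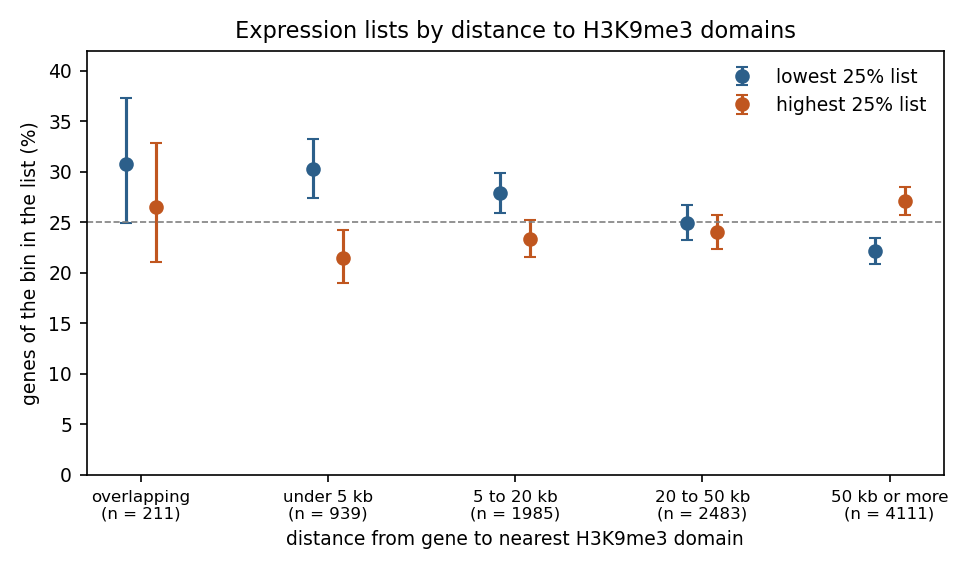
Share of genes in the lowest-expression list (blue) and highest-expression list (orange) by distance from the gene to the nearest H3K9me3 domain in kb, with the number of genes in each bin. Points are percentages of the bin, error bars are Wilson 95% intervals, and the dashed line is the 25% expected by chance; the blue points fall from 30.2% under 5 kb to 22.1% at 50 kb or more.

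Fewer genes of the highest list than of the other lists lay near the ends of the linkage groups, a difference at the edge of significance. Within 100 kb of an end lay 105 genes of the lowest list (4.32%), 101 of the 25-50% list (4.15%), 79 of the 50-75% list (3.25%) and 60 of the highest list (2.47%). For the highest list, the odds ratio against the rest was 0.622 (0.469 to 0.825, exact rotation p = 0.0464), a comparison added after the files were examined and not adjusted for the others. It lost the threshold in 8 of 12 alternatives, among them leaving out linkage group I (0.671, exact rotation p = 0.128) and, each in turn, III, IV, V and VI. For the lowest list it was 1.33 (1.05 to 1.68) and did not pass the exact rotation test (two-sided p = 0.317). With 200 kb as the distance it rose to 1.84 and passed (exact rotation p = 0.0382).

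The listed gene intervals were longer in the highest list than in the lowest. The order of the middle lists was read in part from gene length, so a rise through them is not an independent result. Whether interval length depends on how a gene was annotated was not tested. The unit of the ranking is not given, so whether it was corrected for gene length is unknown. Length may therefore be part of the ranking itself. The median length of the listed interval was 1223 bp in the lowest list (interquartile range 807 to 1829), 2094 bp in the 25-50% list, 2540.5 bp in the 50-75% list and 2717 bp in the highest list (1995 to 3741). The difference between the highest and lowest lists was 1494 bp (permutation test with 100000 resamples, two-sided p = 1e-05, the smallest it can give). Locus tags of NCU10000 and above made up 17.8% of the lowest list and 4.52% of the highest. They were taken here as later gene models, which was not checked.

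Neighbouring genes shared an expression list more often than chance. Of 9722 adjacent pairs, 3197 (32.9%) had both genes in the same list, against 25% on average after permutation and at most 26.6% (permutation test with 10000 resamples, two-sided p = 1e-04, the smallest it can give). The similarity faded with distance, to 30.0% for the next gene but 1, 28.2% for genes 5 apart, 26.7% at 20 and 25.4% at 50. It was strongest among weakly expressed genes, where 1047 pairs of the lowest list stood against 608 expected (1.72-fold), compared with 1.27-fold for the highest list, 1.15-fold for the 50-75% list and 1.12-fold for the 25-50% list; the difference between lists was not tested.

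The longest stretch of the lowest list ran over 48 consecutive genes on linkage group III, from NCU16701 to NCU08569 (4725647 to 4878077, 152 kb). Permuted lists gave at most 12 in a row (permutation test with 1000 resamples, p = 0.000999, the smallest it can give). The permutations do not keep neighbouring genes alike, so how unusual 48 genes are given the clustering above was not tested. The stretch lay between NCU08232 of the highest list and NCU08568 of the 50-75% list, 396 kb from the end of the linkage group. Of its genes, 1, NCU08576, overlapped an H3K9me3 domain. Other long stretches were 22 genes on IV (320439 to 398274, NCU07627 to NCU07648) and 17 on VII (879701 to 933187, NCU06951 to NCU09582). The longest stretch of the highest list was 8 genes on I (2050359 to 2083718), within the range of permuted lists (permutation p = 0.106).

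Genes of heterochromatin formation, which include those deleted in the study, had intermediate expression in the wild type. In the 50-75% list were dim-2, the DNA methyltransferase gene (VII, 3189797 to 3195483), hda-1, which encodes a histone deacetylase (II, 3188786 to 3192710), and hpo, which encodes heterochromatin protein HP1 (VI, 2175752 to 2178135). The H3K9 methyltransferase gene dim-5 (IV, 3480589 to 3482273) was in the 25-50% list. Of the 10 genes of this list, 7 were in the 50-75% list (also cdp-2, dim-7, dim-9 and cul4) and 3 in the 25-50% list (also chap and rid), with none in the highest or lowest list (Fisher's exact test, two-sided, p = 0.0759 and adjusted p = 0.177 for either). Domains reached into cdp-2 by 118 bp and into dim-9 by 620 bp.

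Most histone genes and light-response genes were in the highest list, where the light condition of the cultures behind the ranking is not given in the sources used here. Of 8 histone genes, 7 were in that list: hH3, hH4-1, hH4-2, hH2A, hH2B, hH2Az and hH1 (Fisher's exact test, p = 0.00038, adjusted p = 0.00177). CenH3, the centromeric variant, was in the 50-75% list. The test treats genes as independent, though hH3 lies near hH4-1 on II and hH2A near hH2B on VII. Of 19 genes of the light response and circadian clock, 16 were in the highest list and none in the lowest (Fisher's exact test, adjusted p = 1.37e-06 and 0.0226). They included vvd, the photoreceptor gene whose promoter drives the tagged histone (VI, 2363438 to 2366717), the white collar genes wc-1 and wc-2, the clock gene frq, the carotenoid synthesis genes al-1, al-2 and al-3, the cryptochrome gene cry and the photolyase gene phr. The other 3 were frh in the 50-75% list and con-6 and nop-1, a conidiation gene and an opsin gene, in the 25-50% list. A domain reached into hH2B by 235 bp, into al-3 by 313 bp and into nop-1 by 423 bp. The overlap with hH2B is shorter than 1 step of the 300 bp grid of the domains, and that with al-3 is close to 1 step.

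All 8 housekeeping genes (act, tub-2, tef-1, gpd-1, pma-1, hsp80, his-3 and am) were in the highest list (Fisher's exact test, adjusted p = 0.000106). The remaining lists were small and spread over the ranking, and none passed. Among RNA silencing genes, the Argonaute gene qde-2 and the Dicer gene dcl-1 were in the highest list, qde-1 and dcl-2 in the 50-75% list, qde-3 in the 25-50% list and sms-2 in the lowest list (Fisher's exact test, adjusted p = 0.902 for the highest list). Of the PRC2 genes for H3K27 methylation, npf was in the 50-75% list, set-7 and suz12 in the 25-50% list and eed in the lowest list. Of the nutrient-regulated genes, nit-3 was in the highest list, cbh-1 in the 50-75% list, qa-2 in the 25-50% list and gh5-1 in the lowest list. The 7 lists gave 14 tests, of which 4 passed after Benjamini-Hochberg adjustment.

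**Figure D4:**
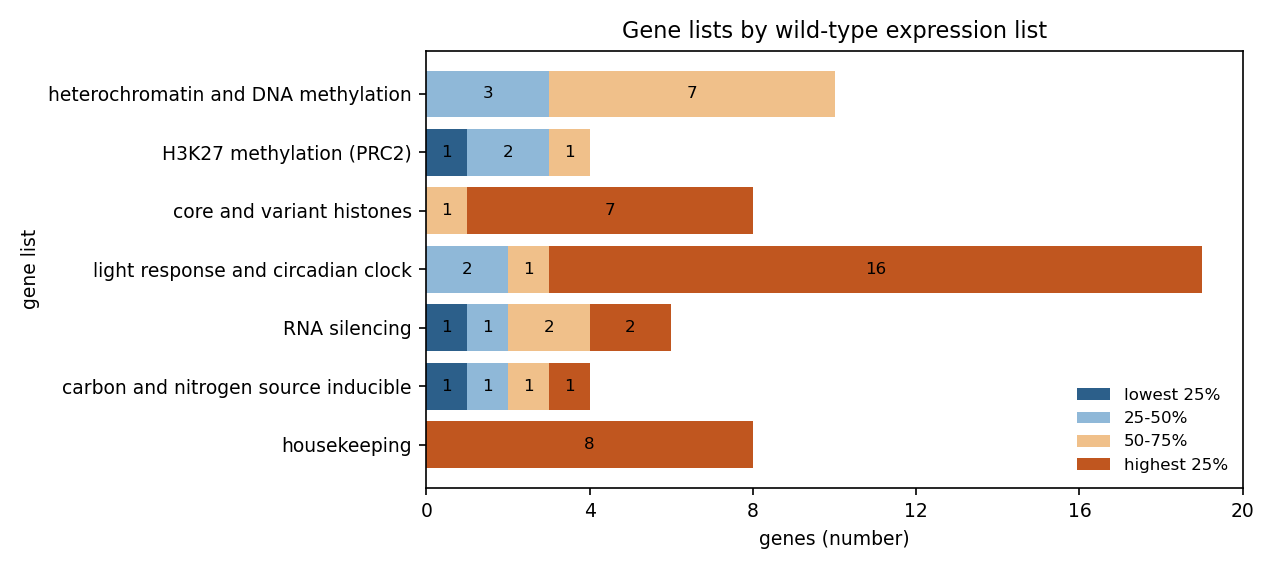
Number of genes of each of the 7 gene lists fixed by gene ID that fell in each wild-type expression list. Bar segments are counts of genes; all 8 housekeeping genes, 16 of 19 light and clock genes and 7 of 8 histone genes are in the highest 25%, and none of the 10 heterochromatin genes is.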

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

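Alternatives chosen after seeing the data were the gene widened by 1 kb on both sides, locus tags below NCU10000, the inverted segment left out, the lists by symbol family, the linkage groups left out for the end comparison of the lowest list, and all alternatives for the end comparison of the highest list and for at least 50% coverage. For domain overlap of the lowest list (main odds ratio 1.34), 15 of 16 alternatives stayed above 1 and short of the threshold, between 1.13 and 1.47. At least 50% coverage passed it at 3.81, and stratifying that by length decile gave 1.53 and ended the call; short genes are more easily covered by a domain, but the share of the change due to length was not separated. The other 10 alternatives for 50% coverage passed, between 3.04 and 6.35. For the highest list (main odds ratio 1.09, no call), the direction reversed to 0.626 at 50% coverage, 0.982 with 1 kb added and 0.970 without linkage group I, and the cause was not tested. The odds ratio of the lowest list for ends passed with 200 kb (1.84) and, at an unchanged 1.33, with Fisher's exact test, which ignores the clustering of neighbouring genes. For the highest list at ends (main odds ratio 0.622), the direction held in 12 of 12 alternatives and the call was lost in 8: with 50 kb (0.591), without overlapping genes (0.629), with locus tags below NCU10000 (0.656) and without linkage group I (0.671), III (0.611), IV (0.620), V (0.640) or VI (0.658); the cause was not tested. The difference in median distance stayed past the threshold in 9 of 9 alternatives (9.17 to 12.0 kb). They were domains of at least 2 kb, overlapping genes left out, and each of the 7 linkage groups left out in turn. Length strata, linkage group strata, genes near ends left out, locus tags below NCU10000 and the inverted segment left out were not tried for it. Gene length and adjacent pairs stayed past the threshold in 2 of 2 alternatives each. The 7 fixed lists gave 4 calls, and also 4 with the threshold on unadjusted p. Testing the upper 50% of the ranking against the lower 50%, with 1 test per list, gave 3. The 17 lists by symbol family, which are other lists, gave 19. Not run were 1 kb upstream only, distance from the gene start and pairs by orientation (no strand in the files), a stricter domain score (no score there), GC content (no genome sequence used here) and lists without product descriptions (none were run); no interval was listed more than once, so removing duplicates changes nothing. No paired analysis was possible because values of the libraries that share replicate numbers were not analysed here. Depth is unknown, and 52 genes with at least 50% coverage limit what the length strata can show.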

Other observations

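Tests in this part were chosen after the results they concern were seen, except the odds ratio at 50% coverage over all genes, the tests of gene families by expression list, the test of genes near domains and the test of row positions of 4 gene families. Gene families taken by symbol after the files were examined separated by expression list in 13 of 17 cases (34 Fisher's exact tests, 19 past the threshold after adjustment). As for the fixed lists, each family was tested against all other genes. Of the 9729 genes, 1118 have a symbol other than the locus tag. Whether the families differ from genes with a symbol in general was not tested. All 29 subunit genes of respiratory complex I, all 17 cell wall protein genes and all 7 ribosomal protein genes named by symbol were in the highest list, with 28 of 30 proteasome, 11 of 13 vacuolar ATPase, 12 of 16 citric acid cycle and 8 of 9 clock-controlled genes. Of 62 serine/threonine kinase genes, 26 were in the highest and 7 in the lowest list, and of 55 genes for amino acid biosynthesis, 24 were in the highest and none in the lowest (Fisher's exact test, adjusted p = 2.45e-06 for the lowest list).

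Several families had few or no genes in the lowest list without filling the highest. Of 27 DNA repair genes, 16 were in the 25-50% list and 1 in the lowest list (Fisher's exact test, adjusted p = 0.015). No gene of mitochondrial import (21 genes, 13 in the 50-75% list), peroxisome biogenesis (20 genes, 10 in the 50-75% list) or histone modification (25 genes, 10 in the 25-50% list) was in the lowest list (Fisher's exact test, adjusted p = 0.00978, 0.015 and 0.00509). All 7 genes of the COP9 signalosome were in the 50-75% list, where no test was run. Glycoside hydrolases (24 of 79 in the lowest list), the quinate cluster (3 of 7) and polyketide synthases (1 of 6) did not pass.

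Genes at least 50% covered by H3K9me3 domains were in the lowest list more often than other genes, with an odds ratio of 3.81. Genes with locus tags of NCU10000 and above do not account for it, since among locus tags below NCU10000 the odds ratio was 3.60 (1.88 to 6.87). Gene length could account for much of it: within length deciles the odds ratio was 1.53 (0.763 to 3.07). The 52 such genes leave a wide interval, which spans 1 and overlaps the unstratified interval (2.20 to 6.61). Whether the ranking was corrected for gene length is unknown, so length may be part of the ranking itself. Reads lost in AT-rich or repeated domain sequence cannot be told apart from low expression for the covered genes, because no sequence or expression value was used; genes under 5 kb from a domain but outside it also leaned to the lowest list (odds ratio 1.35, 1.17 to 1.57), where such loss would not be needed. An effect of the heterochromatin itself remains open, as a dim-5 deletion strain's expression was not analysed here.

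The 48 consecutive lowest-list genes on linkage group III are a second pattern. Genes with locus tags of NCU10000 and above do not explain it, since 41 in a row remained without them. Permutations, which do not keep neighbouring genes alike, gave at most 10 in 1000 resamples. H3K9me3 over the genes themselves does not explain it either, since 2.08% of the genes (1 of 48, 0.369 to 10.9) overlapped a domain. That compares with 2.17% of all genes and up to 35.4% in other stretches of 48. An effect of H3K9me3 nearby stays open: the median distance to a domain was 36.9 kb (19.7 to 54.0) against 32.7 kb for the other lowest-list genes, but a domain of 30.3 kb (III, 4827901 to 4858200) lies inside the run. Sequence missing from the strain stays open too: 14.6% of the 48 genes (7.25 to 27.2) were among the last 440 rows of the list, against 18.1% of the whole list, but this bears on missing sequence only if rows follow expression, which was not established. No biological explanation other than H3K9me3 was tested.

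Rows within the lowest list had an order at the foot. The last 440 rows were a single run of rising locus tags, the longest earlier run in that list had 129 rows, and the other lists ended in runs of 1 or 2. Such runs are consistent with ties in the value the rows were sorted by, kept in locus tag order, but that value is not known. The pooled test fixed beforehand went against an order of falling expression in the highest list: complex I, proteasome, vacuolar ATPase and ribosomal protein genes had a median position at 46.9% of rows (42.1 to 51.7, permutation p = 0.563), where falling expression had been taken to put them near the front. Of 16 gene lists taken singly, 6 had a position past the threshold after adjustment, all far forward. Medians were 1.60% for clock-controlled genes, 7.15% for ribosomal proteins (1 of the 4 pooled families) and 8.26% for housekeeping genes. They were 9.33% for cell wall proteins, 12.2% for histones and 19.6% for glycoside hydrolases. No position was fixed beforehand for single lists. These medians go with falling expression only if the genes are the most expressed, which was not established.

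The 16 light and clock genes of the highest list had a median position at 27.1% of rows (permutation test, adjusted p = 0.082, not past the threshold), from vvd at row 47 to sub-1 at row 2394 of 2433. In the final run of 440 rows of the lowest list, 3.86% of genes overlapped a domain against 2.41% of the other 1993 (odds ratio 1.63, 0.927 to 2.86, Fisher's exact test p = 0.101). The share of genes in the lowest list ranged from 20.1% on linkage group I to 32.2% on VII.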
